A study of Aliger gigas with 11 samples.

How the data were processed

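Single-colour Agilent arrays of ovary RNA from 11 field-collected female queen conch were analysed, 5 from Guana Island, 3 from Rhode Harbour and 3 from Trellis Bay; sites and contamination status came from the labels. Per the labels, total RNA was extracted from ovary with phenol-chloroform and a caesium chloride gradient and labelled with Cy3. The authors deposited scanner output with signal intensity per spot; per the file headers it was made with Agilent Feature Extraction 10.1.1.1, with spatial and multiplicative detrending and with surrogate values for signals not above background. They also deposited a table of log2 values, which the authors' files do not describe. Set against the scanner values, each column ranked probes almost identically (Spearman's rho at least 0.998) and had a median between 9.07 and 9.10. For every array but that of Guana Island animal 5 (85.9%), between 97.0% and 100% of values lay within 0.1 of quantile-normalized log2 processed signals. Its exact normalization is not given in the sources used here.

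From the scanner files, log2 of the processed signal was taken and each array's 75th percentile over the 14958 conch probes subtracted. Control spots and 250 probes of other designs were left out of the tests, and spots marked as non-uniform were set to missing (240 probes lost at least 1 array). Probes well above background on at least 3 arrays (13417) were kept. One mean per site was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), giving contaminated sites (their equally weighted mean) against Guana Island, each contaminated site against Guana Island, Trellis Bay against Rhode Harbour, and an F test over the 3 sites. All tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Variance between arrays was partitioned by permutational analysis of Euclidean distances, with all splits enumerated. Figures were drawn with matplotlib 3.10.9.

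These comparisons, the filter, the threshold, the rule for named probes and most alternatives were chosen before the data were examined. By that rule, without gene names at most 2 probe identifiers higher and 2 lower are given per comparison, here those with the lowest p. It was applied again to the fit of the 6 contaminated-site arrays. The 28 gene lists fixed beforehand were not tested, because the files pair no conch probe with a gene name and no reference was used here. Contig families, probe strand and probe composition were examined after the data were seen.

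Scaling and single arrays mattered for direction. The median log2 difference over all tested probes was -0.01 for contaminated sites against Guana Island, -0.14 for Rhode Harbour, 0.10 for Trellis Bay and 0.27 for Trellis Bay against Rhode Harbour, so single values should be read against these shifts. Of probes at an unadjusted p under 0.05, 60.9% were higher in Trellis Bay than in Rhode Harbour, and this became 73.7% after normexp, 52.1% after quantile normalization 51.5% with the authors' log2 table and 46.6% without Trellis Bay animal 4. For Trellis Bay against Guana Island 58.9% became 76.1% after normexp, 34.2% without Trellis Bay animal 4 and 46.1% without Guana Island animal 5. For Rhode Harbour 43.5% became 54.9% with the authors' table and 60.1% without Rhode Harbour animal 4.

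The number of arrays limits precision: the median 95% interval of a log2 difference was ± 0.805 for contaminated sites against Guana Island, ± 0.971 for each contaminated site, and ± 1.09 for Trellis Bay against Rhode Harbour. The procedure was tested on simulated data with 200 of 13417 probes changed. Values were drawn independently for each probe and array, from normal distributions with the probe's mean and residual SD. The correlation between probes on the real arrays was left out, so the shares below hold for such data only. Per simulation, 3.9 to 7 unchanged probes were called. For contaminated sites against Guana Island it recovered 14.3% of 2-fold, 62.8% of 4-fold and 82.4% of 8-fold changes. The shares were 4.33%, 44.0% and 72.7% for Rhode Harbour against Guana Island, 4.93%, 48.5% and 71.4% for Trellis Bay, and 1.64%, 34.5% and 64.6% for Trellis Bay against Rhode Harbour.

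Arrays lay on 2 slides with 2 rows each, and both were examined as batches. Alternatives were normexp background correction (offset 50), quantile normalization, a percentile over probes well above background on all arrays, the authors' log2 table, no filter and a stricter one, slide as a block, array weights, a spread trend, a replicate block, leaving out each array, fitting only the sites compared, and averaging probes of one target. For shared controls, 100 sets of unchanged groups were simulated from the arrays' residuals, drawn with replacement and random signs. For the overlap the arrays' residuals were shuffled 100 times with random signs.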

Results

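Ovary RNA of adult female queen conch (*Aliger gigas*, a large herbivorous marine snail of the Caribbean, formerly *Strombus gigas*) was measured on single-colour Agilent microarrays made for this species. The animals came from 3 places in the British Virgin Islands. Rhode Harbour (3 animals) and Trellis Bay (3 animals) were contaminated with tributyltin, an organotin compound used in antifouling paints. Guana Island (5 animals) was the site with little pollution. Tributyltin is known to cause imposex, the growth of male organs in female snails, and the comparisons ask whether ovarian transcript levels differed between contaminated and cleaner sites. Each animal had its own array. The arrays carried 14958 conch probes of 60 bases, named by contig or sequencing read and not by gene, so probes are given below by identifier, target and sequence. Levels are log2 signals minus the array's 75th percentile, and their number limits the precision: the median residual SD of a probe within sites was 0.62.

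The 75th percentile of the processed signal averaged 2179 ± 391 (SD, n = 5) intensity units at Guana Island, 2586 ± 395 (SD, n = 3) at Rhode Harbour and 1884 ± 341 (SD, n = 3) in Trellis Bay. It ran from 1553 to 2826 over the 11 arrays, and between 70.5% and 91.7% of conch probes were well above background. Probes well above background on at least 3 arrays numbered 13417, and these were tested. Arrays of the same site correlated with a mean r across probes of 0.919 and arrays of different sites with 0.907; probes are not independent replicates. The array of Trellis Bay animal 2 stood apart, with a mean r of 0.845 with the other arrays. The first principal component held 38.8% of the variance and the second 15.5%. Scores on the first did not separate contaminated from Guana Island arrays (means -1.46 and 1.75, two-sided exact permutation p = 0.952), while by site they were -56.1 ± 62.8 (SD, n = 3) for Trellis Bay, 53.2 ± 7.35 (SD, n = 3) for Rhode Harbour and 1.75 ± 53.2 (SD, n = 5) for Guana Island. They differed between the arrays' positions on the slides, in a test that takes no account of site: the 5 arrays in slide row 2 averaged 46.3 and the 6 in row 1 averaged -38.6 (two-sided exact permutation p = 0.0108, Benjamini-Hochberg adjusted over 3 such tests 0.0325). All 3 Trellis Bay arrays were in row 1, with Guana Island animals 4 and 5 and Rhode Harbour animal 2, whose score was 45.3.

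**Figure D1:**
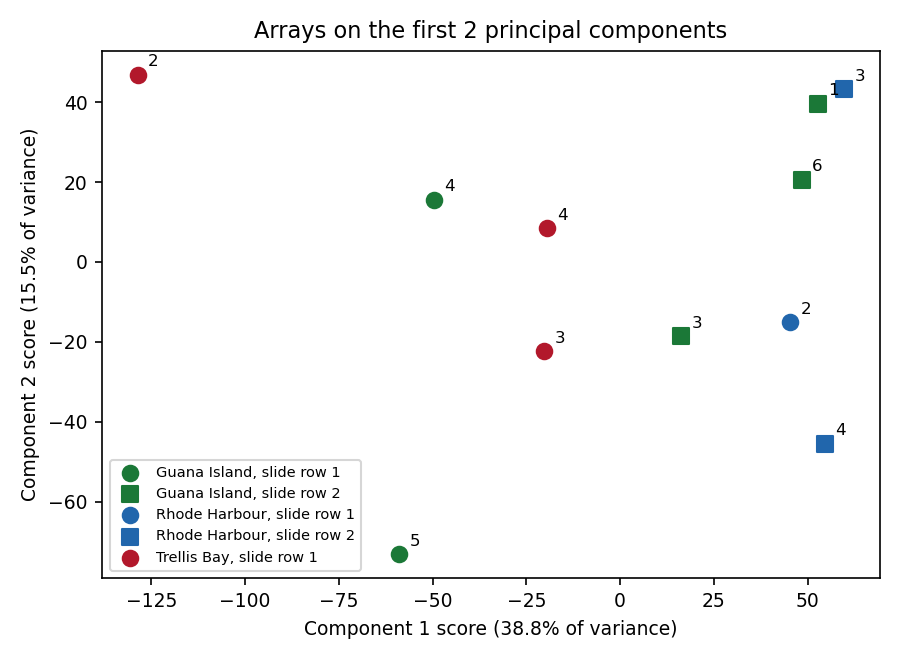
Scores of the 11 arrays on the first principal component (x axis, 38.8% of variance) and the second (y axis, 15.5%), with colour for the site, shape for the slide row and the animal number beside each point. Slide row 2 arrays sit at the right, from 16.2 to 59.8 on the x axis, as does Rhode Harbour animal 2 of row 1, at 45.3, and Trellis Bay animal 2 lies at the far left, at -129.

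No conch probe was found to differ between the contaminated sites and Guana Island. The probe with the lowest p among those higher at contaminated sites, UF_Sgi_CN_111477 (contig Conch.13631.C1, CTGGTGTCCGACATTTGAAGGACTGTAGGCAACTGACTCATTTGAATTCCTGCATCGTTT), had levels of 0.29 ± 0.47 (SD, n = 3) at Rhode Harbour, -0.86 ± 1.09 (SD, n = 3) at Trellis Bay and -2.11 ± 0.47 (SD, n = 5) at Guana Island. Its log2 difference was 1.83 ± 0.39 (SE; limma adjusted p = 0.99986). UF_Sgi_AM_107769 (read ERXZ1SM08EP9AK, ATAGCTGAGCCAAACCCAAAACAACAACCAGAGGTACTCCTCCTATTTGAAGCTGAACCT) gave 0.96 ± 0.25 (SE), or 0.61 after normexp background correction, and UF_Sgi_AF_102560, designed for the other strand of the same read, gave 1.59. On the lower side UF_Sgi_AF_102282 (contig Conch.4224.C1, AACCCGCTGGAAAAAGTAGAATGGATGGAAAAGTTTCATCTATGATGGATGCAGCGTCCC) gave -2.47 ± 0.48 (SE), or -1.03 after normexp background correction, and was well above background on 1 of the 3 Trellis Bay arrays. UF_Sgi_CN_110572 (contig Conch.8840.C1, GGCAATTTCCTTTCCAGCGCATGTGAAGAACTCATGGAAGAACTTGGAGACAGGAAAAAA) gave -2.12 ± 0.54 (SE). None of these values passed the threshold. In limma 0 of 13417 probes passed, and 237 were at an unadjusted p under 0.05, where chance gives 671. That count was 393 without Guana Island animal 4, 396 without Rhode Harbour animal 3 and 157 without Guana Island animal 3. The grouping held 5.69% of the variance between arrays (exact permutation p = 0.976 over 462 splits).

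Rhode Harbour and Guana Island did not differ at any probe past the threshold. UF_Sgi_CN_111477 again had the lowest p among the higher probes, with a log2 difference of 2.40 ± 0.47 (SE). UF_Sgi_CN_110538 (contig Conch.4751.C1, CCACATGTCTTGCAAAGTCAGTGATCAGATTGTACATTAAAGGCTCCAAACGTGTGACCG) gave 2.04 ± 0.40 (SE), from -2.59 ± 0.79 (SD, n = 3) at Rhode Harbour against -4.63 ± 0.52 (SD, n = 5), and was well above background on 2 of the 5 Guana Island arrays. Its difference was 0.95 after normexp background correction. On the lower side, UF_Sgi_AM_108529 (read ETMYUMG02GOC88, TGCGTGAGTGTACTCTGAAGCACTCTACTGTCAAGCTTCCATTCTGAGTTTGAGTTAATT) gave -1.69 ± 0.38 (SE), and the probe for its other strand, UF_Sgi_AF_105502, gave -1.03. UF_Sgi_AF_100356 (read ERXZ1SM08EUYB4, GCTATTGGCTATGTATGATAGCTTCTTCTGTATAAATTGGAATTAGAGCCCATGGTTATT) was not well above background on any Rhode Harbour array and was on 2 of 5 Guana Island arrays. With the signals of the other 3 taken as measured, its Guana Island mean was at least 1.31-fold higher, a bound taken against the lowest signal among probes well above background on each Rhode Harbour array. All 4 had an adjusted p of 0.858 in limma. There, 0 of 13417 probes passed and 644 were at an unadjusted p under 0.05. Chance gives 671 on average, and the median over the other splits of these arrays was 468. Without Rhode Harbour animal 4 the count was 401. The sites accounted for 16.6% of the variance between these 8 arrays (exact permutation p = 0.268 over 56 splits).

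Trellis Bay and Guana Island likewise showed 0 of 13417 probes past the threshold in limma, with 613 at an unadjusted p under 0.05. UF_Sgi_CN_112126 (contig Conch.555.C1, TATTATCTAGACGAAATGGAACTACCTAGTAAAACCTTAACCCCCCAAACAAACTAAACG) was at 0.43 ± 1.06 (SD, n = 3) in Trellis Bay and -2.42 ± 0.59 (SD, n = 5) at Guana Island, a log2 difference of 2.85 ± 0.49 (SE; limma adjusted p = 0.770). UF_Sgi_AM_107769 gave 1.48 ± 0.30 (SE), and its other-strand probe 1.67. UF_Sgi_AF_102282 gave -3.50 ± 0.57 (SE), or -1.05 after normexp background correction, and was well above background on 1 of the 3 Trellis Bay arrays. UF_Sgi_CN_110572 gave -3.52 ± 0.65 (SE), from -3.26 ± 1.36 (SD, n = 3) against 0.25 ± 0.84 (SD, n = 5). No value here passed. The count of 613 moved in both directions when single arrays were left out. It fell to 351 without Trellis Bay animal 2. It rose to 1066 without animal 3, 958 without animal 4, 1155 without Guana Island animal 4 and 969 without Guana Island animal 5. Without Trellis Bay animal 4, 1 probe passed the threshold. The sites accounted for 16.0% of the variance (exact permutation p = 0.25 over 56 splits).

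Trellis Bay and Rhode Harbour did not differ at any probe past the threshold when all 11 arrays were fitted. UF_Sgi_CN_114835 (contig Conch.5098.C1, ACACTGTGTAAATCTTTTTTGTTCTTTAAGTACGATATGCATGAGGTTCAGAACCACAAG) was at -5.47 ± 0.999 (SD, n = 3) in Trellis Bay and -0.55 ± 0.34 (SD, n = 3) at Rhode Harbour, a log2 difference of -4.92 ± 0.97 (SE; limma adjusted p = 0.274); after normexp background correction the difference was -2.22. It was well above background on 1 of the 3 Trellis Bay arrays. Guana Island lay between, at -3.19 ± 1.77 (SD, n = 5). UF_Sgi_CN_113046 (contig Conch.1929.C1, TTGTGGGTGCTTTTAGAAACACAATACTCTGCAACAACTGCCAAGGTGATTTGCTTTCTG) gave -2.29 ± 0.44 (SE). Among the higher probes, UF_Sgi_CN_114639 (contig Conch.14933.C1, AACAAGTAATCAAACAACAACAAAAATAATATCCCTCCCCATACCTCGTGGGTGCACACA) gave 2.32 ± 0.43 (SE) and UF_Sgi_CN_112126 gave 2.92 ± 0.55 (SE). In limma 0 of 13417 probes passed, and 2248 were at an unadjusted p under 0.05, 1368 higher and 880 lower in Trellis Bay, where chance gives 671. Without Trellis Bay animal 4 the share of higher ones was 46.6%. That count of 2248 was 976 without Trellis Bay animal 2, 1487 without Rhode Harbour animal 2 and 1416 without Rhode Harbour animal 4. The grouping by site held 38.0% of the variance, with an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. All 3 Trellis Bay arrays were in slide row 1 and Rhode Harbour animals 3 and 4 in row 2, so this share cannot be credited to site alone.

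**Figure D2:**
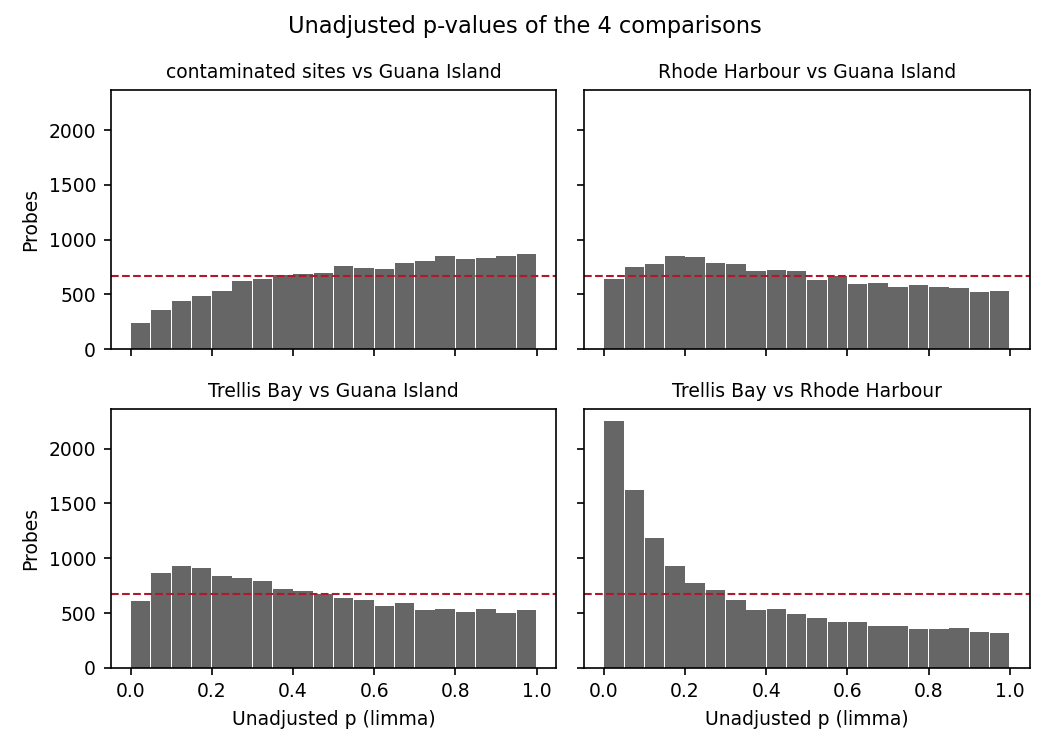
Number of probes (y axis) by unadjusted limma p in steps of 0.05 (x axis) for the 4 comparisons, with a dashed line at 671, the count chance gives per step. The first step holds 237, 644, 613 and 2248 probes, and only Trellis Bay against Rhode Harbour exceeds the line there.

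**Figure D3:**
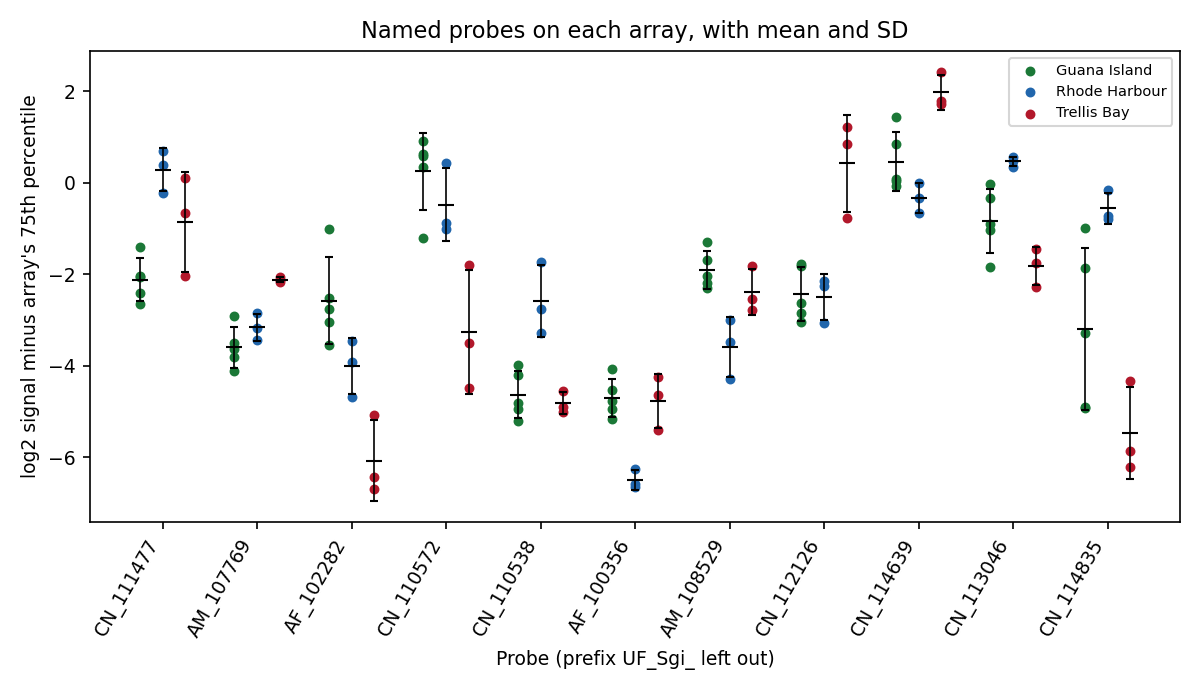
Levels of the 11 named probes (y axis, log2 signal minus the array's 75th percentile) on each array, with colours for the sites and bars for the mean and SD. UF_Sgi_CN_112126 is at 0.43 in Trellis Bay, where it was well above background on all 3 arrays, and at -2.42 at Guana Island.

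Fitted on the 6 arrays of the contaminated sites alone, Trellis Bay and Rhode Harbour differed at 61 probes, of which 59 were lower and 2 higher in Trellis Bay (limma, lowest adjusted p = 0.0119). UF_Sgi_AF_101098 (read ES8A9FR01A2H7P, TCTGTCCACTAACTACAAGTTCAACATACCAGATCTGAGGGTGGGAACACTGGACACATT) was at -0.39 ± 0.55 (SD, n = 3) at Rhode Harbour and -5.83 ± 0.63 (SD, n = 3) in Trellis Bay, where 1 of the 3 arrays was well above background. UF_Sgi_AF_100424 (read ETMYUMG02G2X7X, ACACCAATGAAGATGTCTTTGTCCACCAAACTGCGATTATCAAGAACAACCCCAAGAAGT) stood at 3.67 ± 0.13 (SD, n = 3) at Rhode Harbour and -1.03 ± 0.11 (SD, n = 3) in Trellis Bay. The 2 higher probes were UF_Sgi_CN_110610 (contig Conch.13091.C1, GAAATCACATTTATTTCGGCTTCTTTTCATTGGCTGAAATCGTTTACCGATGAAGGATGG), by 3.71 ± 0.40 (SE), and UF_Sgi_AF_104841 (contig Conch.8935.C1, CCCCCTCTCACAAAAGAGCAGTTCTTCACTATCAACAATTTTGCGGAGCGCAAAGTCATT), by 2.31 ± 0.32 (SE). Over the 61 probes the median SD was 1.98 among Guana Island arrays, against 0.42 at Rhode Harbour and 0.42 in Trellis Bay. Over all tested probes these medians were 0.56, 0.45 and 0.54. The fit that chose the 61 favours a small spread within Rhode Harbour and Trellis Bay. On the Guana Island arrays, 45 of the 59 lower probes correlated over 0.9 with their mean, against 748 of 13126 other probes. The 59 are thus not separate results. The Guana Island mean lay between the other sites at all 61. These calls were not stable: 0 probes passed in limma when any of Trellis Bay animals 2 and 3 or Rhode Harbour animals 2, 3 and 4 was left out (1371 to 2682 at an unadjusted p under 0.05), and 26 passed without Trellis Bay animal 4, of which 17 were among the 61. With slide as a term 0 passed, with 1665 at an unadjusted p under 0.05. Without those animals the lowest adjusted p in limma ran from 0.066 to 0.095, and with slide it was 0.073. Fewer arrays or an added term also lower precision, so the lost calls do not show that the differences were absent. Slide row as a term gives no usable contrast here, since Rhode Harbour animal 2 is the only one of its site in the row of the Trellis Bay arrays.

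**Figure D4:**
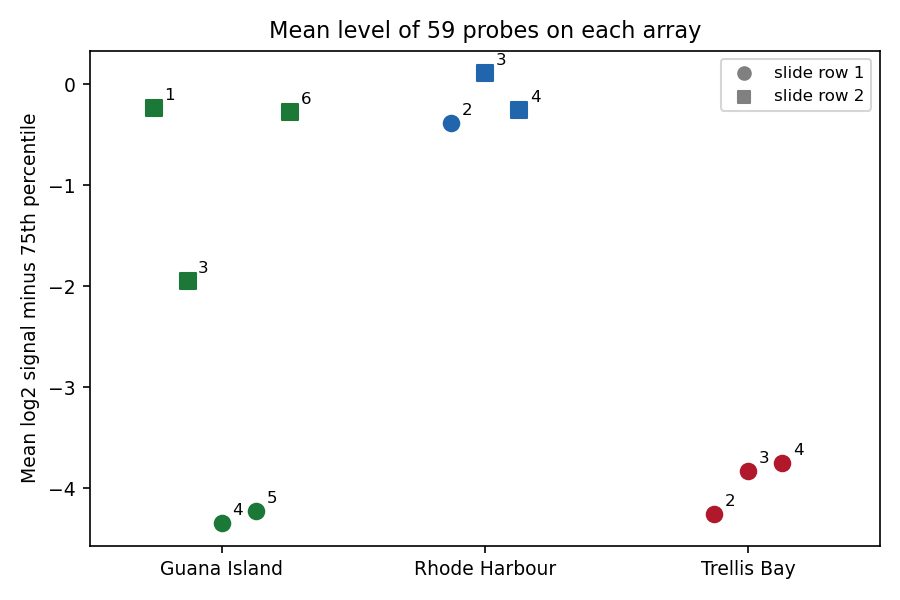
Mean level (y axis, log2 signal minus the array's 75th percentile) of the 59 probes called lower in Trellis Bay, on each array of the 3 sites (x axis), with shape for the slide row and the animal number beside each point. Guana Island arrays, which had no part in choosing the probes, were at -4.34 and -4.22 in slide row 1 (animals 4 and 5) and at -0.24, -1.95 and -0.28 in row 2 (animals 1, 3 and 6).

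Slide and slide row were examined as batches. Fitted alone in limma, slide row had 0 probes past the threshold and 2559 at an unadjusted p under 0.05, and slide had 4 and 1205; with sites in the model these were 0 and 1259 for row and 0 and 920 for slide. The 4 probes, named after their values were seen, were all lower on slide 2 (limma adjusted p = 0.0455), UF_Sgi_CN_111981, UF_Sgi_AF_102915 and UF_Sgi_AF_104376 by log2 differences of -2.36, -2.51 and -1.88. The first was well above background on 1 of the 5 slide 2 arrays. UF_Sgi_AF_101970 was on none of these and on 5 of the 6 of slide 1, and was at least 1.54-fold higher on slide 1 by the same bound. No probe passed in limma in any site comparison with either as a block. With slide as a block, the counts at an unadjusted p under 0.05 were 273 for contaminated sites against Guana Island, 550 for Rhode Harbour, 598 for Trellis Bay and 1713 for Trellis Bay against Rhode Harbour. With slide row as a block they were 327, 709, 400 and 839. Slide 1 and row 1 each held 1 Rhode Harbour array, slide 2 held 1 Trellis Bay array and row 2 none, too few for the comparisons that need them. The others within a batch were Trellis Bay against Guana Island, with 601 in slide 1 and 233 in row 1, and Rhode Harbour against Guana Island, with 495 in slide 2 and 349 in row 2.

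Whether the contaminated sites departed from Guana Island alike could not be decided. Across 13417 probes, which are not independent replicates, the log2 differences of Rhode Harbour and Trellis Bay from Guana Island had r = -0.26, whereas unchanged groups sharing the same controls gave a simulated mean of 0.334 with an SD of 0.364. The covariance was -0.11 against a simulated 0.13, a difference of -0.24. With separate Guana Island arrays for each site, r averaged -0.38 and ranged from -0.68 to -0.03. Signs matched at 38.0% of probes, against 61.4% simulated. At an unadjusted p under 0.05 in both comparisons, 4 probes were higher and 14 lower, where unchanged groups sharing controls gave means of 63.4 (simulated SD 97.3) and 78.4 (simulated SD 111). All simulated values are from the 13185 probes missing on no array. The r lay within the simulated range of -0.90 to 0.91. That simulation drew the arrays' residuals with replacement and random signs, so the same array could enter several groups. Almost any r would lie in so wide a range, so this decides nothing. Each slide, and row 1, held only 1 array of 1 of the contaminated sites, too few for an r within them to be read; with slide row as a block it was 0.0464, and without Trellis Bay animal 2 it was -0.00108. A moderated F test over the 3 sites gave 0 of 13417 probes in limma, with 1112 at an unadjusted p under 0.05; that count was 657 without Trellis Bay animal 2, 733 without Rhode Harbour animal 2 and 671 without Rhode Harbour animal 4. All 3 sites together held 27.3% of the variance (exact permutation p = 0.104 over 4620 splits). Adjusted over the 5 such tests, the exact permutation p-values were 0.976, 0.335, 0.335, 0.260 and 0.260, in the order contaminated sites, Rhode Harbour, Trellis Bay, Trellis Bay against Rhode Harbour, and all sites.

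No contig family passed a test of joint change. Of 23 families with at least 5 probes, grouped after the data were seen, 0 passed limma's camera with an estimated correlation, 0 with a preset one, and 0 passed fry in any comparison; at an unadjusted camera p under 0.05 there was 1 family between Trellis Bay and Rhode Harbour and 0 elsewhere. That family was Conch 458, whose 10 probes had a median log2 difference of -0.69, with 3 higher (camera adjusted p = 0.670).

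The arrays also carried 250 probes of other organisms' designs. Of these, 76.8% were well above background on at least 3 arrays, compared with 89.7% of conch probes. Their median level was -3.17, against -2.01 for conch probes, and 15.5% of conch probes lay above their 95th percentile.

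**Figure D5:**
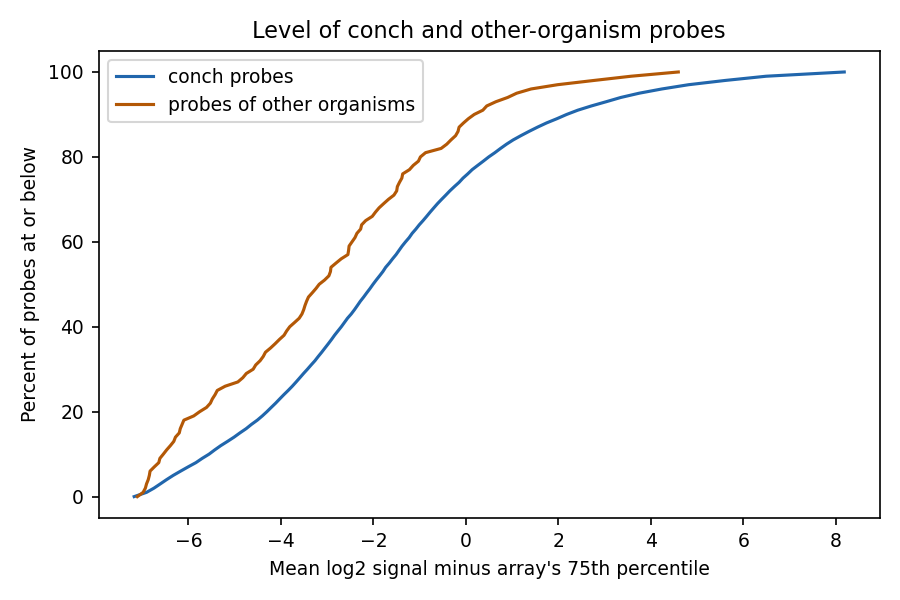
Percent of probes (y axis) at or below a mean level (x axis, log2 signal minus the array's 75th percentile) for conch probes and for probes of other organisms. The conch curve lies to the right at the quartiles, with -3.84, -2.01 and -0.06 against -5.38, -3.17 and -1.39.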

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

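The comparison of the dimmer strand's probes with probes of other organisms was chosen after its result had been seen; the other tests in this part were chosen before theirs were seen.

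Probe UF_Sgi_CN_110572 had a level of -1.21 in Guana Island animal 5, far from the other 4 animals of that site, which lay between 0.36 and 0.91. This was 1 of 17 measures examined for a lone distant array, and chance marks about 1 in 20.

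Probes of other organisms gave signal in data outside the comparisons: a median of 70% of the 250 were well above background over the 11 arrays. Brightness of the slide surface is argued against, since 0.945% of negative control spots were well above background. Those spots are not ordinary probes, so they cannot decide on nonspecific signal of any probe, which stays open. Pyrimidine content of the probe may contribute, since the share of C and T correlated with level across these probes (Spearman's rho 0.651, permutation p = 1e-04, the smallest that 10000 resamples can give). It was not the only such measure: the share of G and C correlated too (Spearman's rho 0.326, permutation p = 1e-04). Across the 14958 conch probes the share of C and T also correlated with level (Spearman's rho 0.474). Cross-hybridisation of conserved conch transcripts was not tested, nor was any biological explanation.

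Among 1146 targets with a probe for each strand, 81.6% had both probes well above background on at least 3 arrays. The dimmer probes had a median level of -3.32, inside the interquartile range of other organisms' probes (-5.38 to -1.39), and over 1101 of the pairs the median correlation across arrays was 0.0587, where the 95th percentile of 1000 random re-pairings was 0.0696 and their SD 0.0161.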

How the results depend on the processing

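Fits with slide row as a block, within a slide or slide row, with only probes above the 95th percentile of other organisms' probes, and all variations of the 6-array fit were chosen after seeing the data. Over 29 alternatives, 134 of 139 counts of probes past the threshold stayed at 0 in limma. Of the values of named probes, 422 of 423 kept their direction and their side of the threshold, with 0 reversed. These probes were chosen from the same data for the lowest p in each direction. Several alternatives also leave an estimate unchanged by design, so the kept directions say little about robustness. UF_Sgi_CN_114835 passed for Trellis Bay against Rhode Harbour with only those sites in the fit (adjusted p = 0.0278; 0.0572 to 0.944 under the other alternatives). That fit gave 61 probes; it has fewer arrays and leaves out the Guana Island spread. In the 6-array fit quantile normalization gave 93 probes (57 shared), the authors' values 91 (58 shared) and no filter 58. With the replicate block, 1 probe passed for Rhode Harbour against Guana Island, 1 for Trellis Bay against Rhode Harbour and 1 over the 3 sites. No pairing of animals by number was seen: same-numbered arrays' deviations correlated from -0.14 to 0.11, and 0 of 8 arrays correlated best with their own number. With 7 pairs this cannot exclude such pairing. Leaving out each array gave 0 to 1 probes for Trellis Bay against Guana Island. The correlation between the contaminated sites' differences, -0.26, ranged from -0.33 to -0.00108 on leaving out each array, the latter without Trellis Bay animal 2. It was 0.0231 with array weights, 0.200 with the replicate block and 0.0464 with slide row as a block. Within slide 1, slide 2 and row 1 it was -0.25, 0.239 and 0.321, each with 1 array for a site and so too few to read; the cause was not tested. Counts at an unadjusted p under 0.05 were highest with array weights (855, 1755, 1438, 3945 and 2591 for contaminated sites, Rhode Harbour, Trellis Bay, Trellis Bay against Rhode Harbour and all sites) and lowest among probes above the 95th percentile of other organisms' probes, where fewer were tested (43, 91, 137, 460 and 203 of 2778). Gene list tests were not run, the contaminated-site contrast already uses all sites, and row 2 alone allowed only Rhode Harbour against Guana Island. The signal of other organisms' probes, whose source was not settled, limits the rest: 17.3% of tested probes exceeded their 95th percentile. That level is not background: all tested probes were well above background on at least 3 arrays, and 69.8% on all 11.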

Other observations

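For Trellis Bay against Rhode Harbour, both counts of splits and slide row as a term were chosen after the result was seen. The fit without Trellis Bay animal 2 was planned, but its bounds as a test and the size of the differences in it were chosen after.

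Among the Guana Island animals, the 59 probes called lower in Trellis Bay than in Rhode Harbour took levels as far apart as those of the contaminated sites. Animals 4 and 5 averaged -4.34 and -4.22, near the Trellis Bay arrays at -4.25, -3.83 and -3.75. Animals 1 and 6 averaged -0.24 and -0.28, near Rhode Harbour at -0.39, 0.11 and -0.26, and animal 3 lay between at -1.95. Of the 61 probes called, 4 had a mean level above the 95th percentile of other organisms' probes.

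Slide row is a candidate explanation of the 61 calls: Guana Island arrays in row 1 averaged 3.46 lower over the 59 probes (a difference of -3.46), the largest of the 10 splits (exact permutation p = 0.1, the smallest possible). Rhode Harbour animal 2, also in row 1, was at -0.39, but it is 1 array and helped choose the probes, so it excludes nothing. Of the 10 splits of the 6 arrays, 1 gave as many probes past the threshold, the real one with 61 against 2 in the highest other, and 10 splits are too few for a share under 0.05. Site, slide row and differences between animals that the labels do not record remain open, the biological ones untested.

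For the 2248 probes at an unadjusted p under 0.05 between Trellis Bay and Rhode Harbour, less strand-specific hybridisation on the Trellis Bay arrays stays open, since their mean gap between strands was 0.0233 wider with an SE of 0.120. The row of the array on its slide could account for part. The signed difference between Guana Island arrays of rows 1 and 2 had a median of 0.64 against 1.39 between the sites. It had the same sign at 85.3% of these probes. That share rests on a single comparison of 2 Guana Island arrays with 3, so its probes are not separate results. With row as a term the count was 839, but row overlaps with site, so lost precision alone could lower it. The array of Trellis Bay animal 2 alone left 976 when dropped, above the 671 chance gives, and the 2248 probes then had a median signed difference of 1.12 (median SE 0.52) against 1.39 (median SE 0.50), although they were chosen with that array. Of 10 splits, 1 gave as many, the real one with 2248 against 1399 in the highest other, too few splits for a share under 0.05. Both 839 and 976 lie between the count chance gives and the bound set for excluding row or that array. Those limits treat probes as independent, whereas another of the splits gave 1399, so neither count can decide. Row, that array and site each stay open.

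Chance could not be excluded for the other counts at an unadjusted p under 0.05. For contaminated sites against Guana Island 86 of 100 drawn splits gave as many as 237, with 2459 in the highest other. For Rhode Harbour against Guana Island it was 18 of 56 (644, highest other 2328), for Trellis Bay against Guana Island 25 of 56 (613, highest other 2566), and for the 3 sites 7 of 100 drawn (1112, highest other 2891). Over the splits other than the real one, the median count was 450, 468, 561 and 480 in that order. Some splits called many probes past the threshold where the real one called 0 in limma: up to 215, 223 and 364 for Rhode Harbour, Trellis Bay and the 3 sites. The split with 2566 and 223 set the row 2 Guana Island animals 1, 3 and 6 against the row 1 arrays of Guana Island and Trellis Bay. It follows slide row exactly. The top splits for contaminated sites and Rhode Harbour followed slide row in most arrays. In each, Rhode Harbour animal 2 was the only row 1 array of the group drawn as Guana Island. The only row 2 array of the other group was Rhode Harbour animal 3 for contaminated sites and Guana Island animal 3 for Rhode Harbour. The top split for the 3 sites mixed rows in 1 group only, through Rhode Harbour animal 2. Its other groups were all of row 1 and all of row 2. With row as a block, Trellis Bay against Guana Island had 400 probes at an unadjusted p under 0.05.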
